A study of Zea mays with 9 samples.

How the data were processed

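Gene-level read counts of 9 libraries from maize B73 were analysed. Per the labels' protocols, plants were grown in a greenhouse and self-pollinated, whole kernels were taken at 0, 2, 3, 4 and 6 DAP and endosperm free of embryo and pericarp at 8, 10 and 12 DAP, poly(A) RNA was selected in 2 rounds, and libraries were made for the SOLiD 4 system. The labels state that 1 of 3 collected biological replicates per stage was sequenced, and that the 2 libraries of 0 DAP are technical replicates.

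The values are raw read counts as deposited by the authors, 1 column of whole numbers per library over the same 110028 gene models, of which 33946 had no read in any library. Per the submitters' processing notes bedtools was used, with its version and role not given in the sources used here. The aligner, the genome build, the annotation release and the treatment of reads that fit several places are not given in the sources used here either. Some reads may have been counted in more than 1 model: 1033 models form 445 groups whose counts agree within 2% in every library and reach 100 reads, and these models held 2.49% to 3.87% of reads up to 8 DAP, 23.3% at 10 DAP and 39.5% at 12 DAP. Strand was not used.

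Gene names came from a table of RefSeq genes of assembly Zm-B73-REFERENCE-NAM-5.0, which was used for names only and without coordinates. It matched 18787 of the model identifiers, 17155 of them in a record tied to 1 identifier, and 2219 models had a usable name that no other model carried. Names matched to several models were left out. No product descriptions were held in the table, so list members were found by symbol. The 25 gene lists fixed before the data were examined were extended by symbol families and joined by 16 further lists after the name table was read and before any counts were compared between stages. Of the 41 lists 39 were tested, and the others had 1 and 0 detected members.

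Effective library sizes were computed with edgeR 4.0.16 (TMM, calcNormFactors over the 9 libraries) in R 4.3.3, and v is the CPM of effective reads. The 0 DAP sample is the sum of its technical replicates. A gene passed between 2 stages when (v + 1) differed by a ratio of at least 4, the higher v was at least 10, and the exact conditional binomial 95% interval of the ratio excluded 1. At v = 10 the interval rests on 547 reads at 6 DAP and 56.8 at 12 DAP, and 3 reads correspond to v = 0.0549 and 0.528. The 4 block comparisons required this of every pair of stages across the blocks. Reads are not independent molecules, so intervals and floors cover counting error only. Where a stage had no read, the fold is a lower bound against 3 reads at that stage. The fold and interval given for a block comparison are of the pair of stages with the smallest ratio. A list's change is the median over its detected members (v of at least 1 in a library) of the difference in mean log2(v + 1), and its percentile comes from 10000 random lists matched in 20 expression bins. Percentiles from 97.5 or to 2.5 are described as high or low. With 39 such medians in each of the 4 comparisons, some fall there by chance. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

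Genes were named by a rule fixed before the data were examined: the 10 higher and 10 lower named genes with the largest ratio that pass each block comparison, the 4 members of each list with the largest change, and all matched members of a list of key genes. Genes outside this rule are said to have been named after their values were seen. The rule of size was tested on simulated counts of 110028 models, drawn from the mean of each model with the dispersion of the technical pair (0.0304), with 200 changed genes. These genes were chosen among models with a mean v of at least 10. The rates below therefore do not cover lower genes, which the minimum level can keep from passing. For 12 against 8 DAP it recovered 0% of genes changed 2-fold, 45% of those changed 4-fold, 85% at 6-fold and 100% at 8-fold. For endosperm against kernels it recovered 0%, 0%, 47.5% and 100%, and for early against unpollinated kernels 0%, 20%, 90% and 100%. These simulations hold no difference between biological samples, so they give no rate of false calls between stages. The list percentile called 6 of 100 unchanged lists of 20 genes and 100 of 100 lists moved by 1 on the log2 scale. The simulated genes were drawn at random and varied independently, so this gives no rate for lists of genes that vary together.

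Alternatives were DESeq2 1.42.0 size factors, library totals with and without the zein list, no minimum level, a ratio of 2, a pseudocount of 0.1, counts thinned to the smallest library total, each technical replicate alone and each stage not required. Totals without the zein list leave out its 29 models only, so unlisted models of like counts stay in them. Chosen after seeing the data were library totals without the 100 most counted models, 1 model per group of like counts, subtraction of late endosperm reads from the 0 to 4 DAP libraries, and leaving out models that differ between the technical replicates. Coordinates, sequence and splice forms were not analysed here.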

Results

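The transcriptome of the maize inbred B73, the genotype of the reference genome, was measured by SOLiD RNA sequencing of poly(A) RNA through the first 12 days after self-pollination (DAP). Whole kernels were sampled at 0, 2, 3, 4 and 6 DAP, and endosperm dissected free of embryo and pericarp at 8, 10 and 12 DAP. The endosperm is the nutritive tissue of the seed, which starts as a multinucleate cell, becomes cellular and differentiates, and then fills with starch and storage protein. Each stage was represented by 1 biological sample, and the 0 DAP sample was sequenced as 2 technical replicates (a and b), so 9 libraries covered 8 stages. The libraries held 17716275 (0 DAP, a), 25291158 (0 DAP, b), 20408282 (2 DAP), 22858089 (3 DAP), 19754760 (4 DAP), 40145710 (6 DAP), 17915299 (8 DAP), 30091846 (10 DAP) and 36543449 (12 DAP) counted reads. With 1 sample per stage no difference between stages has a biological replicate, and no p-value is given. Genes were called higher or lower by a fixed rule of size on the normalised read count v, the TMM-scaled CPM: a ratio of at least 4 on v + 1, a higher value of at least 10, and an exact 95% interval of the ratio that excluded 1. The intervals cover counting error only.

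Of 110028 gene models, 44687 reached v = 1 in at least 1 library, and between 31031 (12 DAP) and 33515 (6 DAP) did so in each library. At this cut the number of detected models changed little, whereas the distribution of reads over them changed greatly. The cut follows the scaling and asked for fewer reads at 12 DAP than at 6 DAP. Models with at least 1 read numbered 63824 at 6 DAP and 45260 at 12 DAP. The 10 most counted models held 1.52% and 1.33% of reads in the 0 DAP replicates and 1.83% at 6 DAP, but 7.10% at 8 DAP, 23.5% at 10 DAP and 40.8% at 12 DAP. The 100 most counted models held 9.43%, 19.6%, 55.5% and 85.8% at 6, 8, 10 and 12 DAP. The 29 genes of the zein list, which are prolamin storage proteins of the maize endosperm, accounted for 1.24%, 18.4% and 30.1% of reads at 8, 10 and 12 DAP. The list holds only models with a usable name, so this is not the share of all zein models. Unlisted GRMZM2G514485, whose counts are within 2% of those of the listed z1A1_5, held 4.46% at 12 DAP, which may be the same reads counted again. Models in groups of like counts held 39.5% of counted reads at 12 DAP. Among the most counted were GRMZM2G059620 and GRMZM2G586611 with 4.47% each. The shares of the 10 and 100 most counted models at 10 and 12 DAP may therefore include reads counted more than once. After TMM scaling v = 10 accordingly corresponded to 56.8 reads at 12 DAP and to 547 reads at 6 DAP. A v of a zein at 12 DAP is thus relative to the bulk of genes and is not a share of the library.

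**Figure D1:**
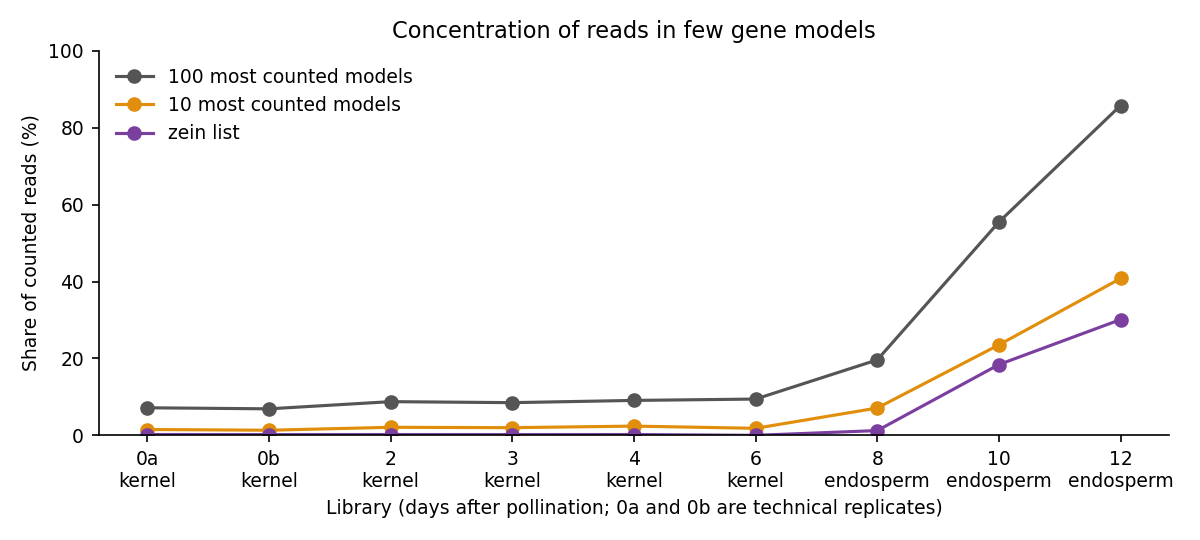
Share of counted reads (%, vertical axis) held by the 10 and the 100 most counted gene models and by the zein list in each of the 9 libraries (horizontal axis, days after pollination and tissue). The share of the 100 most counted models is 9.43% in the 6 DAP kernel library and 85.8% in the 12 DAP endosperm library. Reads that fit several models of like counts may be included more than once.

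Across the 44687 detected models, the technical replicates had a Spearman correlation of 0.956 and a Pearson correlation of 0.969 on log2(v + 1). Pairs of different kernel stages from 0 to 4 DAP had Spearman correlations of 0.896 to 0.921, and 6 DAP correlated best with 4 DAP (0.895). The 6 and 8 DAP libraries, which differ in both age and tissue, correlated at 0.795, while 8 with 10 DAP and 10 with 12 DAP gave 0.883 and 0.888. These correlations are across genes, which are not independent replicates.

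The technical replicates show how far 2 libraries differ without any difference in age or tissue. By the rule of size 77 genes differed between them, 57 higher in b and 20 higher in a. Some were near absent from 1 library, such as GRMZM5G828705 with 0 reads in a and 2448 in b. GRMZM2G366795 had 445 reads in a and 1 in b. The source of such differences was not tested. The SD of the log2 ratio was 0.56 for genes at a mean v of 1 to 10, 0.37 at 10 to 100 and 0.26 above 100. The squared deviation over the variance of Poisson counting had a mean over genes of 13.1, 24.3 and 78.7 in these 3 ranges, and a median of 4.76, 7.68 and 23.5. The counting intervals given for single genes are therefore narrower than the spread between libraries of the same RNA.

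Each stage was compared with the stage before it. From 0 to 2 DAP 173 genes were higher and 258 lower. From 2 to 3 DAP the counts were 154 and 144, from 3 to 4 DAP 184 and 104, and from 4 to 6 DAP 354 and 223. The step from 6 to 8 DAP, which is also the change from whole kernel to dissected endosperm, held 746 higher and 1436 lower genes, 2182 in all and more than any other step under TMM, whereas by library total it held 2824 and the step from 10 to 12 DAP 2830. Within the endosperm 401 genes were higher and 304 lower from 8 to 10 DAP, and 298 were higher and 228 lower from 10 to 12 DAP. The technical pair shares its RNA, so its 77 genes do not include differences between biological samples of 1 stage, which were not measured. The higher and lower counts in the later steps depended on the scaling: by library total alone they were 566 and 2258 from 6 to 8 DAP, 210 and 1147 from 8 to 10 DAP, and 12 and 2818 from 10 to 12 DAP. With totals that left out the zein list they were 575 and 2232, 246 and 752, and 52 and 2138. With totals that left out the 100 most counted models of each library, an alternative chosen after seeing the data, the last step gave 313 and 360.

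**Figure D2:**
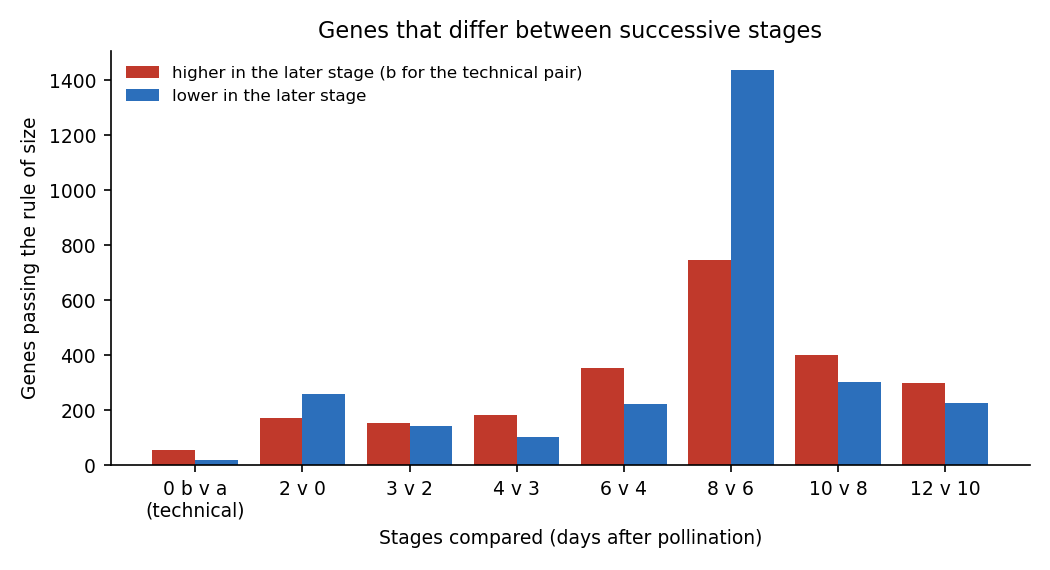
Number of genes (vertical axis) that passed the rule of size as higher or lower in the later of 2 successive stages (horizontal axis, days after pollination), with the technical replicates of 0 DAP at the left. The 8 against 6 DAP step has 746 higher and 1436 lower genes, and the technical pair has 57 and 20.

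To ask what follows pollination, the 2, 3 and 4 DAP kernels were each compared with the unpollinated 0 DAP kernels. At all 3 stages at once, 41 genes were higher and 41 lower than at 0 DAP. The gene mn1 (GRMZM2G119689), which encodes the cell wall invertase that cleaves incoming sucrose at the base of the endosperm, had v = 2.53 at 0 DAP and 20.3, 20.1 and 13.3 at 2, 3 and 4 DAP, a smallest rise of 5.26-fold (95% interval 4.39 to 6.33). AGP2, an ADP-glucose pyrophosphorylase subunit gene of starch synthesis, rose from 97.4 to between 429 and 472, with a smallest ratio of 4.40-fold (95% interval 4.27 to 4.53). The auxin genes ARF17, an auxin response factor, and AUX3 rose from 10.2 to between 51.1 and 65.9 and from 3.10 to between 16.5 and 32.9. The beta-expansin gene expB6, whose product loosens cell walls, rose from 2.04 to 11.7 at 2 DAP and 106 at 4 DAP. The phytosulfokine precursor psk1 rose from 1.13 to between 17.9 and 25.3, the ribosomal protein gene rpl30 from 0.617 to between 35.1 and 63.1, and id1 from 2.92 to between 15.5 and 17. Lower genes with a name were the sucrose synthase gene sus2 (GRMZM2G318780), which fell from 177 to 9.81, 4.00 and 2.43, and COL5, which fell from 26.1 to between 3.53 and 4.28. No other named gene passed.

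Gene lists showed broader and smaller shifts after pollination than the rule of size. The percentile of a list's median among 10000 random lists of the same size and expression describes these libraries only. The 33 cytosolic ribosomal protein genes had a median log2 change of 0.71, above all random lists, with 28 above 0 and 1 passing the rule. The 15 DNA replication genes had a median of 0.60 (percentile 99.95), with 13 above 0 and none passing, as for pcna1, the sliding clamp of DNA polymerase, at 18.5, 58.5, 41.3 and 30.9. The 13 tubulin and other cytoskeleton genes had a median of 0.64 (percentile 99.8), the 46 auxin genes 0.36 (percentile 99.98), the 18 endoplasmic reticulum folding genes 0.49 (percentile 99.1) and the 23 cell wall expansion genes 0.37 (percentile 98.7). The 8 proteases of cell death (0.60, percentile 99.3), 17 aquaporins (0.49, percentile 99.9), 7 flavonoid pathway genes (0.50, percentile 99) and 17 SBP factors (0.33, percentile 97.8) also lay high. The 12 NAC transcription factors lay low (-0.37, percentile 1.37). The 5 core histone genes had a median of 0.72 (percentile 96.8) and the 19 mitosis and cyclin genes -0.06 (percentile 24.5), both within the middle 95% of random lists. The block counts rested on single stages: without the requirement at 2, 3 or 4 DAP the higher genes numbered 85, 74 and 54 and the lower genes 62, 75 and 84. By library total they were 62 higher and 70 lower.

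At 6 DAP, the last whole-kernel stage, genes of 2 domains of the differentiating endosperm rose. Against all of the 2, 3 and 4 DAP kernels at once, 230 genes were higher and 71 lower at 6 DAP. Of the 16 detected genes of the basal transfer layer, the cells that take up nutrients from the mother plant, 12 rose, and the list's median log2 change was 4.43, above all random lists. The antimicrobial peptide genes betl2 (GRMZM2G152655) and bap-3a rose from between 2.14 and 7.01 to 341 and from between 0.494 and 1.15 to 154, with smallest ratios of 48.6-fold (95% interval 42.8 to 55.5) and 134-fold (95% interval 97.9 to 188). The maternally expressed gene meg1 rose from between 0.922 and 2.33 to 71, and betl10, bap-1a, bap1-b and bap-3b reached 101, 117, 81.8 and 105. The model matched to mrp1, the MYB-related activator of this layer, did not pass and had v between 0.954 and 6.41 over all stages. All 5 genes of the embryo-surrounding region lay above their 2 to 4 DAP mean and 4 rose, among them esr2 (between 0.230 and 3.47 to 97.3) and esr6 (between 0 and 0.169 to 23).

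Other named genes that rose at 6 DAP were the imprinted Polycomb gene fie1, from between 0.0329 and 1.92 to 12.3, the granule-bound starch synthase gene wx1, from between 1.03 and 3.41 to 18.6, BURP7, from between 3.52 and 6.27 to 149.7, and the auxin-conjugating GH3, from between 0.560 and 0.810 to 16. The cystatin gene cc8 rose to 63.2, the beta-expansin expB7 to 16.4, the defence gene PR10 to 16, the asparagine synthetase asn3 to 13.1 and the factor bZIP84 to 72.4. The 23 genes of the jasmonate synthesis list, which were found by symbol and include lipoxygenases of other routes such as lox3, had a median of 0.87 and the 8 proteases of cell death 1.01, both above all random lists, although no member of either passed the rule. Lists that also lay high were defence and protease inhibitors (0.56, percentile 99.94, 2 of 21 genes higher), heat shock (0.71, percentile 99.9), cell wall expansion (0.46, percentile 99.7), AP2/ERF factors (0.45, percentile 99.6), Polycomb and imprinted genes (0.55, percentile 98.4, 2 of 8 higher), cytosolic ribosomal proteins (0.29, percentile 98.3), endoplasmic reticulum folding (0.36, percentile 98.1) and endosperm transcription factors (0.57, percentile 97.53). DNA replication (-0.52, percentile 0.06), mitosis and cyclins (-0.32, percentile 1.06) and growth-regulating factors (-0.39, percentile 0.700) lay low, with no member passing.

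Of the genes lower at 6 DAP, 18 belonged to the zein list. After subtraction of late endosperm reads from the 0 to 4 DAP libraries, in shares fitted on the zeins themselves and chosen after seeing the data, 232 genes were higher and 48 lower, 5 of them zeins. z1A1_5 (GRMZM2G053120) had between 192 and 204 at 2 to 4 DAP and 0.274 at 6 DAP, and fl2, an alpha-zein gene, between 52.5 and 59.8 and 0.0366. The starch gene sh2, an ADP-glucose pyrophosphorylase subunit, had between 18.3 and 24.7 and 2.03. Over the 27 zeins with v of at least 1000 at 12 DAP, the value at 0, 2, 3 and 4 DAP was at the median 0.0605% to 0.0686% of that at 12 DAP in each of the 5 libraries, and 0% at 6 DAP. Several zein models, z1A1_5 and zp27 among them, have counts within 2% of another model in every library and may share reads. Without the requirement at 4 DAP 374 genes were higher, and the lower genes numbered 117 and 120 without that at 3 or 4 DAP.

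Dissected endosperm was set against whole kernels by asking that all 3 endosperm stages stand above or below all 5 kernel stages. Here 201 genes were higher and 216 lower. Of the 29 zein genes 24 were higher (16 by library total), with a median log2 change of 8.25. The gamma-zein zp27 (GRMZM2G138727) went from at most 7.93 in kernels to 746, 2059 and 5544 at 8, 10 and 12 DAP, and the beta-zein zp15 from at most 14.2 to 1057, 3115 and 9701. Of 21 starch synthesis genes 8 were higher (4 by library total), with a median of 2.60. The sucrose synthase gene sh1 had between 83.4 and 142 in kernels and 1394, 11774 and 15451 in endosperm, sh2 at most 24.7 and then 1781, 6865 and 16648, bt2 at most 16.1 and then 122, 2378 and 2558, and the plastid adenylate transporter gene bt1 at most 1.69 and then 121, 663 and 807. The starch branching enzyme gene SBEIIb, wx1, pho1 and sugary2 were the other 4, of which pho1 and sugary2 were named after their values were seen. The smallest ratios were 9.82-fold (95% interval 9.60 to 10.1) for sh1 and 72-fold (95% interval 66.9 to 77.6) for sh2.

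Of 8 endosperm transcription factors 4 were higher, and by library total 1 was, o2. The bZIP activator of zein genes o2 (GRMZM2G015534) had at most 0.540 in kernels and 36.7, 203 and 251 in endosperm. The aleurone regulators nkd1 and nkd2 reached between 44.2 and 63.6 and between 29.6 and 41.7, and Opaque11 between 30.9 and 38.2 from 5.36 at 6 DAP. The list's median was 2.19, and ohp1, ohp2 and mrp1 had log2 changes of -1.17, -0.60 and -0.59 without passing. fie1 (between 61.6 and 116) and the imprinted gene nrp1 (between 80.9 and 226) were the 2 Polycomb and imprinted genes that passed, out of 8, and by library total fie1 did not pass. The auxin synthesis genes yuc and tar3 had 231, 146 and 151 and 13, 76.5 and 122.8, against at most 2.32 and 0.206 in kernels. The legumin gene leg1, the pyruvate phosphate dikinase gene CYPPDKZM2, hag, the NAC factor nac4, BURP7 and the oil body gene ole1 also rose, to 1750.2, 2258, 141, 126, 2150.4 and 62.7 at 8 DAP, of which BURP7 did not pass by library total. Of the 16 transfer layer genes betl-9 alone passed the rule here, and by library total none did. The list's median was 4.88. The embryo-surrounding region had a median of 2.15 with 4 of 5 genes above 0 and none passing, and embryo and oil bodies 1.53, above all random lists, with 1 of 13 passing. Cytosolic ribosomal proteins had a median of 1.13 (31 of 33 above 0) and heat shock 0.88 (percentile 99.8), but by library total these medians were -0.46 and -0.42.

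Genes lower in endosperm included regulators of floral organs. All 9 genes of the maternal reproductive MADS list lay below their kernel mean (median -2.80, below all random lists) and 3 fell by the rule. The floral organ identity gene zag1 (GRMZM2G052890) had between 57.8 and 85.7 in kernels and between 4.57 and 8.62 in endosperm, zmm8 between 249.8 and 400.2 and between 3.34 and 18.1, and zmm7 between 465 and 676 and between 42.7 and 102. Of the 25 MADS-box factors 6 fell (median -2.41), including zmm29 and MADS18, with smallest ratios of 12-fold (95% interval 9.46 to 15.3) and 10.4-fold (95% interval 8.98 to 12). DL1 fell from between 88.6 and 165 to between 1.20 and 3.52, the benzoxazinoid synthesis gene BX5 from between 61.1 and 206 to between 1.62 and 3.58, bHLH30 from between 60.5 and 91.1 to between 1.41 and 2.99, the lipid transfer protein gene LTP3 from between 89.2 and 372 to between 4.53 and 8.44 and the alpha-expansin EXPA5 from between 28.9 and 47 to between 0.470 and 1.06. The lipoxygenase genes lox1 and lox11, the soluble invertase gene ivr2, the glutamine synthetase gene gln3, the beta-glucosidase gene glu2 and bHLH116 fell too.

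Several list medians lay low in endosperm. Jasmonate synthesis (-1.72, 2 of 23 lower, the lipoxygenase genes lox1 and lox11), cell wall expansion (-1.35, 3 of 23) and auxin (-0.95, 2 lower and 2 higher of 46) lay below all random lists. Also low were bHLH factors (-0.93, percentile 0.01), growth-regulating factors (-1.12, percentile 0.03), homeobox factors (-0.82, percentile 0.04), MYB factors (-0.56, percentile 0.250), SBP factors (-0.63, percentile 1.46), nitrogen assimilation (-1.37, percentile 0.07), mitosis and cyclins (-0.84, percentile 0.08), proteases of cell death (-1.31, percentile 0.1), cell number regulators (-0.67, percentile 0.350), the flavonoid pathway (-1.09, percentile 0.535) and the cytoskeleton (-0.65, percentile 1.12). Of these, 3 bHLH factors and 1 gene each of the growth-regulating factors, nitrogen assimilation, proteases and flavonoid lists fell, and no gene of the homeobox, MYB, SBP, mitosis and cyclin, cell number and cytoskeleton lists passed. Age and tissue are confounded in this comparison, since no whole kernel was sampled after 6 DAP and no endosperm before 8 DAP. The split of 201 higher and 216 lower genes became 72 and 601 by library total, 83 and 562 with totals without the zein list, and 194 and 417 with totals without the 100 most counted models. Without the requirement at 8 DAP it was 507 and 327, without that at 6 DAP 346 higher, and without that at 0 DAP 325 lower.

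**Figure D3:**
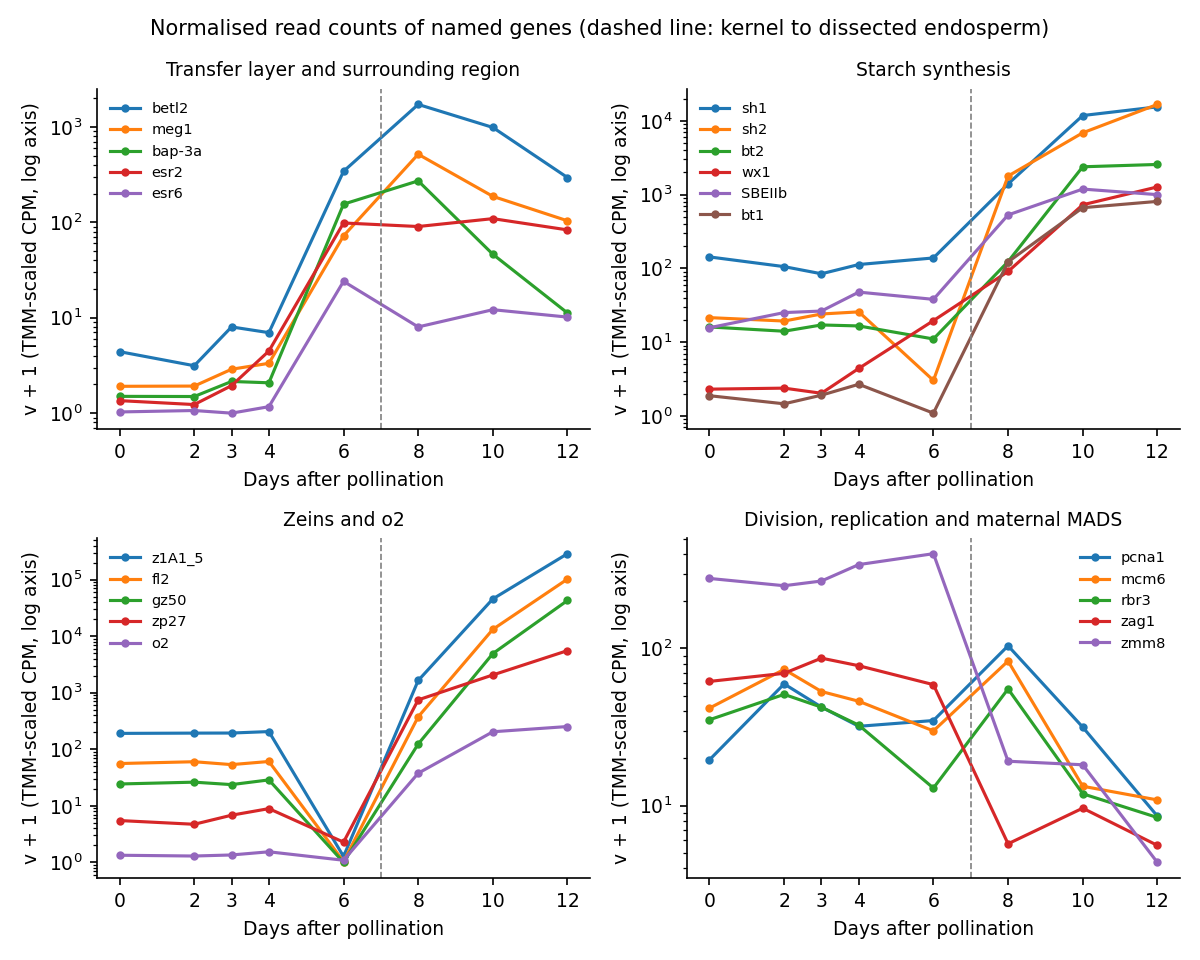
Normalised read counts (v + 1, TMM-scaled CPM, logarithmic vertical axis) of named genes by days after pollination, 1 sample per stage, with the dashed line between whole kernels and dissected endosperm. In v, before 1 is added, betl2 is at 5.97 at 4 DAP, 341 at 6 DAP and 1714 at 8 DAP, and z1A1_5 is at 0.274 at 6 DAP and 286795 at 12 DAP; by library total the rises of o2 and bt1 from 8 to 12 DAP are not seen (log2 -0.0039 and -0.046).

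Within dissected endosperm, 691 genes were higher and 806 lower at 12 than at 8 DAP. All 29 zeins rose under TMM and 26 by library total, with a median log2 change of 7.85 under TMM. The alpha-zein z1A1_5 went from 1642 at 8 DAP to 45485 at 10 DAP and 286795 at 12 DAP, a rise of 175-fold (95% interval 173 to 177). fl2 went from 374 to 102047, gz50, a gamma-zein, from 122.7 to 42703, and z1B_9 from 21.1 to 13936. zp27 and zp15 rose less, by 7.43-fold (95% interval 7.29 to 7.58) and 9.18-fold (95% interval 9.03 to 9.33), and neither passed by library total, with log2 changes of 0.11 and 0.42. In starch synthesis 8 of 21 genes rose and 1 fell (median 0.76, above all random lists), whereas by library total 0 rose and 7 fell, with a median of -1.78. Under TMM bt2 rose by 20.9-fold (95% interval 20.01 to 21.8), wx1 by 14.1-fold (95% interval 13.4 to 14.9), agpsl1 by 13.4-fold (95% interval 12.6 to 14.4), sh1 by 11.1-fold (95% interval 10.9 to 11.2) and sh2 by 9.35-fold (95% interval 9.23 to 9.47), with most of the rise between 8 and 10 DAP for bt2 (122, 2378 and 2558) and agpsl1 (53.5, 669 and 719). By library total the log2 changes of bt2, wx1, agpsl1, sh1 and sh2 were 1.60, 1.03, 0.96, 0.69 and 0.45, and none of them passed. The sucrose synthase gene sus1, named after its values were seen, fell, from 395 to 83.2. o2 rose from 36.7 to 251, nac4 from 126 to 744, the ribosome-inactivating protein gene rip1 from 3.24 to 211, the protease inhibitor gene MPI from 26.5 to 289 and tar3 from 13 to 122.8, though by library total rip1 alone of these 5 passed, with log2 changes of -0.0039 for o2, -0.21 for nac4, 0.65 for MPI and 0.43 for tar3. The model matched to GIF2 (GRMZM2G154169) had between 42.9 and 48.3 up to 8 DAP and 15233 at 12 DAP, and whether it shares reads with another abundant transcript was not checked here. The cystatin gene cc6 had no read at 8 DAP and 24.5 at 12 DAP, at least 156-fold higher against 3 reads at 8 DAP, and it did not pass by library total. Endoplasmic reticulum folding had a median of 0.33 (percentile 98.7, but -2.34 by library total) with no gene passing.

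Part of the genes of DNA replication, mitosis and the transfer layer fell from 8 to 12 DAP. Of 15 DNA replication genes 8 fell (median -2.26), including pcna1 from 103 to 7.56, 13.6-fold (95% interval 10.1 to 18.9), pcna2 from 56 to 4.93, and the replicative helicase genes mcm6 and mcm7 from 82.1 to 9.85 and from 113 to 15.8. Of 5 core histone genes 4 fell (median -2.44), such as H3C2 from 18.7 to 1.41. Of 19 mitosis and cyclin genes 5 fell (median -1.01), among them cyc3, cyclin4 and the retinoblastoma-related gene rbr3 (54.3 to 7.39). Of 13 cytoskeleton genes 4 fell (median -1.46), such as tub5 from 47.9 to 5.63. Of 16 transfer layer genes 10 fell (median -2.18), including bap-3a from 270.3 to 10.2, 26.5-fold (95% interval 20.5 to 34.9), betl2 from 1714 to 293 and meg1 from 515 to 103, while betl-9 was at 1063 and 1057. Cytosolic ribosomal proteins lay low (-0.79, percentile 0.02, 2 of 33 lower), as did the maternal reproductive MADS genes (-1.21, percentile 0.180) and MADS-box factors (-0.55, percentile 1.16).

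The direction of many of these changes is relative to the scaling. Against TMM, scaling by library total moved the median log2 change of genes with v of at least 10 by -2.33 for 12 against 8 DAP and by -1.51 for endosperm against kernels, and DESeq2 size factors moved it by 0.09 in both. By library total 161 genes were higher and 11394 lower at 12 DAP, with totals without the zein list 177 and 9121, and with totals without the 100 most counted models 726 and 1222. Totals without the zein list still hold unlisted models that count like listed zeins, such as GRMZM2G514485 with 4.46% of reads at 12 DAP. They therefore do not show the shift with all zein reads removed. Under library totals the medians of starch synthesis and endoplasmic reticulum folding were -1.78 and -2.34, and o2, bt1, nac4, PIP2-1, bZip112, ole17, MADS11 and psk1, which rose under TMM, had log2 changes of -0.0039, -0.046, -0.21, -0.17, -0.25, -0.11, -0.032 and -0.69.

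**Figure D4:**
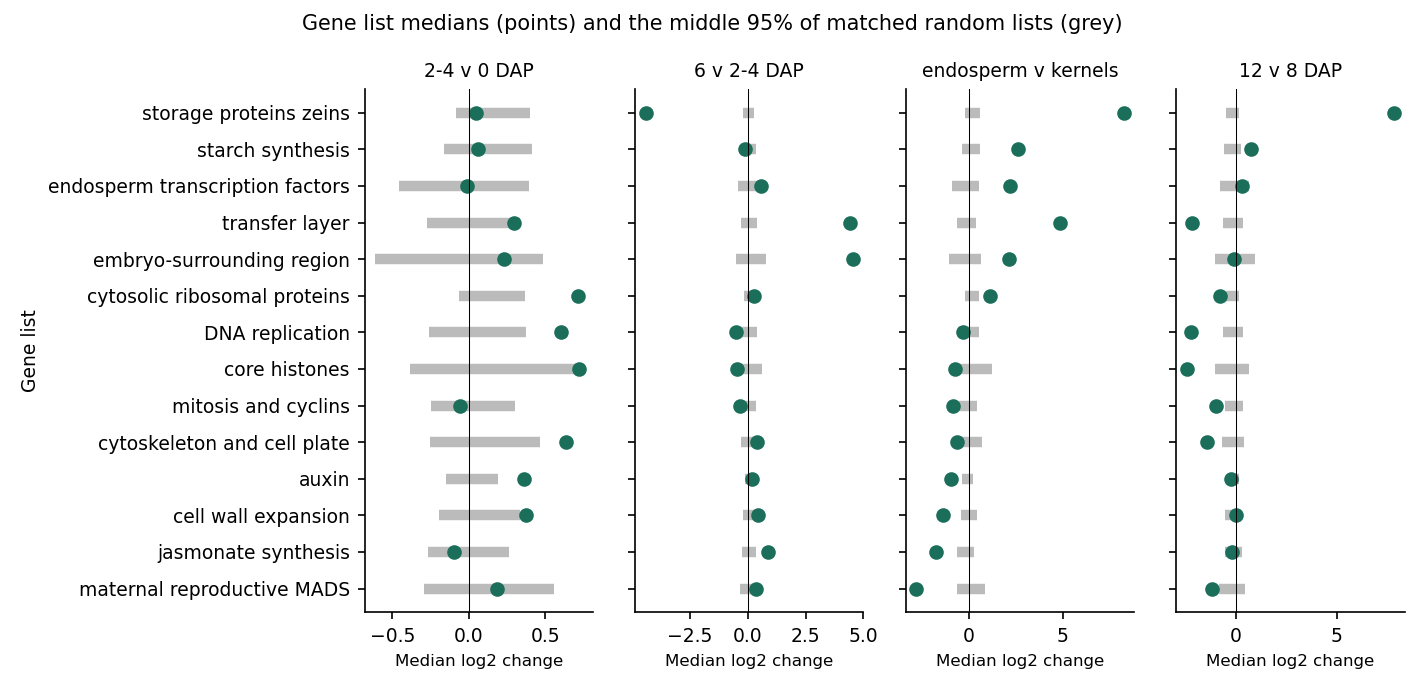
Median log2 change of 14 gene lists (points, horizontal axes) in each of the 4 comparisons, with the middle 95% of 10000 matched random lists in grey. Zeins are at 7.85 and DNA replication genes at -2.26 for 12 against 8 DAP; by library total the medians of starch synthesis for 12 against 8 DAP and of ribosomal proteins for endosperm against kernels change sign, to -1.78 and -0.46.

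Each gene was given to the stage of its maximum where the maximum was at least 10 and at least 4 times the median over stages. Of 2126 such genes, 710 peaked at 12 DAP, 371 at 10 DAP, 308 at 8 DAP and 344 at 6 DAP. Fewer peaked at 0 DAP (185), 2 DAP (85), 3 DAP (48) and 4 DAP (75). This order depended on the scaling, since by library total 484 genes peaked at 0 DAP, 166 at 2 DAP, 92 at 3 DAP, 135 at 4 DAP, 477 at 6 DAP, 385 at 8 DAP, 164 at 10 DAP and 150 at 12 DAP. It also depended on the stages sampled, 5 of kernels and 3 of endosperm. A gene high at a like level in all 5 kernel stages has a high median and cannot pass. One high in all 3 endosperm stages only can pass, so part of the excess of endosperm peaks is built into the rule. Tissue beyond the endosperm was tracked with marker lists. The embryo and oil body list had a median of 1.53 in endosperm against kernels, above all random lists, and at 10 DAP its oil body genes ole1 and ole17 had 239 and 24.9 and the globulin gene Glb1-0 17.4. Most members were low, however: the median v over the list was 1.57, 4.21 and 1.76 at 8, 10 and 12 DAP. At 12 DAP 3 reads correspond to 0.528. The globulin gene glb3, which is outside the list and was named after its values were seen, had 122 at 12 DAP. The embryo regulator lec1 had at most 0.0732 and vp1 at most 1.70, while the meristem gene kn1 had between 3.61 and 10.1 from 0 to 4 DAP and between 0.314 and 0.878 from 6 DAP on. Of 15 photosynthesis genes 4 were detected, and their medians of -0.14, -0.04, -0.75 and 0.12 in the 4 comparisons lay within the middle 95% of random lists. The 6 detected aleurone genes had 0.52 in endosperm against kernels, with nkd1 and nkd2 higher (percentile 90.5). The 26 detected key genes had medians of 0.16, -0.04, 3.22 and 0.11 in the 4 comparisons, and the third was above all random lists. The single gene of the lipid transfer protein list had v = 372 at 3 DAP and 8.44 at 12 DAP, and none of the 3 female gametophyte genes was detected. In their extended versions, the lists with no median outside the middle 95% of random lists in any comparison were cytokinin (25 genes), sugar transport and cleavage (8), aleurone (6), photosynthesis (4), WRKY factors (14) and bZIP factors (26).

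All list medians above are of the extended versions where there is one, and for some lists the shorter version fixed before the data were examined fell on the other side of the limits of the middle 95%. For early against unpollinated kernels these medians were DNA replication 0.62 (percentile 97.2, 4 genes), endoplasmic reticulum folding 0.70 (percentile 90.5, 3 genes), auxin -0.09 (percentile 35.8, 5 genes) and defence and protease inhibitors 0.63 (at the upper limit itself, 3 genes). For 6 DAP against early kernels these medians were endosperm transcription factors 0.55 (percentile 96, 7 genes), endoplasmic reticulum folding 0.75 (percentile 97.2, 3 genes), sugar transport and cleavage 1.53 (percentile 99.9, 4 genes), auxin 1.22 (percentile 99.8, 5 genes), cytokinin 1.32 (percentile 98.3, 2 genes) and defence and protease inhibitors -0.55 (percentile 4.46, 3 genes). For endosperm against kernels these medians were endosperm transcription factors 0.29 (percentile 85.2, 7 genes), Polycomb and imprinted genes 0.97 (percentile 99.3, 7 genes), endoplasmic reticulum folding 2.24 (percentile 99.1, 3 genes), auxin 0.35 (percentile 86.2, 5 genes) and defence and protease inhibitors -1.54 (percentile 0.490, 3 genes). For 12 against 8 DAP this median was endoplasmic reticulum folding 0.76 (percentile 96.4, 3 genes).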

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

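The alternatives that changed a choice after the data were seen are the totals without the 100 most counted models, the single model per group of like counts, the subtraction of late endosperm reads and the removal of models that differ between the technical replicates. DESeq2 size factors, thinning to the smallest total, 1 model per group of like counts, the subtraction and the removal left all 15 counts of the block comparisons and steps within 1.5 times. Genes lower at 6 DAP than in early kernels numbered 48 after the subtraction, against 71.

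With a ratio of 2 in place of 4, the higher and lower genes numbered 305 and 403 (early against unpollinated kernels), 829 and 331 (6 DAP against early kernels), 575 and 677 (endosperm against kernels) and 1947 and 2725 (12 against 8 DAP endosperm). The steps then held 2337 (2 v 0 DAP), 1163 (3 v 2 DAP), 1282 (4 v 3 DAP), 2398 (6 v 4 DAP), 6410 (8 v 6 DAP), 2580 (10 v 8 DAP) and 2208 (12 v 10 DAP) genes. The technical pair then differed at 322 genes. With no minimum level, the higher and lower genes numbered 77 and 62 (early against unpollinated kernels), 360 and 103 (6 DAP against early kernels) and 1088 and 1364 (12 against 8 DAP endosperm). The steps then held 818 (2 v 0 DAP), 680 (3 v 2 DAP), 627 (4 v 3 DAP), 984 (6 v 4 DAP), 3308 (8 v 6 DAP), 1200 (10 v 8 DAP) and 949 (12 v 10 DAP) genes. The technical pair then differed at 186 genes. A pseudocount of 0.1 gave 65 higher genes for early against unpollinated kernels. Peak stages numbered 7614 with a maximum of at least 2 times the median.

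By library total, the higher and lower genes numbered 62 and 70 (early against unpollinated kernels), 72 and 601 (endosperm against kernels) and 161 and 11394 (12 against 8 DAP endosperm). The steps then held 674 (2 v 0 DAP), 466 (3 v 2 DAP), 460 (4 v 3 DAP), 1357 (10 v 8 DAP) and 2830 (12 v 10 DAP) genes. With totals without the zein list, the higher and lower genes numbered 62 and 70 (early against unpollinated kernels), 83 and 562 (endosperm against kernels) and 177 and 9121 (12 against 8 DAP endosperm). The steps then held 674 (2 v 0 DAP), 467 (3 v 2 DAP), 460 (4 v 3 DAP) and 2190 (12 v 10 DAP) genes. With totals without the 100 most counted models, the higher and lower genes numbered 76 and 71 (early against unpollinated kernels), 295 and 112 (6 DAP against early kernels), 194 and 417 (endosperm against kernels) and 726 and 1222 (12 against 8 DAP endosperm). The steps then held 756 (2 v 0 DAP), 538 (3 v 2 DAP) and 525 (4 v 3 DAP) genes. For 12 against 8 DAP, tests of the cause of the shift by library total are given with the other observations, and for the other comparisons the cause was not tested.

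Leaving out 1 stage or technical replicate gave 54 to 85 higher genes for early against unpollinated kernels with 1 stage not required, 54 to 59 higher genes for early against unpollinated kernels with 1 technical replicate, 62 to 84 lower genes for early against unpollinated kernels with 1 stage not required, 47 to 48 lower genes for early against unpollinated kernels with 1 technical replicate, 241 to 374 higher genes for 6 DAP against early kernels with 1 stage not required, 104 to 120 lower genes for 6 DAP against early kernels with 1 stage not required, 202 to 507 higher genes for endosperm against kernels with 1 stage not required, 198 to 203 higher genes for endosperm against kernels with 1 technical replicate, 227 to 327 lower genes for endosperm against kernels with 1 stage not required and 213 to 222 lower genes for endosperm against kernels with 1 technical replicate. The 2 against 0 DAP step held 437 to 531 genes with 1 technical replicate.

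Sign changes were counted only for list medians outside the middle 95% of random lists and for named genes that passed the rule under TMM. By library total the medians of this kind that changed sign were those of cytosolic ribosomal proteins (-0.46) and heat shock (-0.42) for endosperm against kernels, and of starch synthesis (-1.78) and endoplasmic reticulum folding (-2.34) for 12 against 8 DAP. Among the named genes that passed for 12 against 8 DAP, the log2 changes that changed sign were those of PIP2-1 (-0.17), o2 (-0.0039), psk1 (-0.69), bZip112 (-0.25), MADS11 (-0.032), bt1 (-0.046), nac4 (-0.21) and ole17 (-0.11), and with totals without the zein list that of psk1 (-0.20). Of 156 list medians, library totals moved another 73 by at least 0.26 and a pseudocount of 0.1 moved 42, DESeq2 size factors moved 0 and the subtraction 2. This limit is the SD of the log2 ratio of single genes between the technical replicates at a mean v above 100. It does not measure the spread of a list median. With random lists not matched on expression, 4 of the 156 lost and 8 gained a place outside the middle 95%. The depth limits low genes most at 12 DAP, where v = 10 is 56.8 reads. No paired analysis was possible because each stage has 1 biological sample.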

Other observations

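Genes that peaked at 6 DAP, chosen here after their values were seen, include 3 lipoxygenase genes and the allene oxide synthase gene aos1. lox1, lox3 and lox6 had 210.2, 83 and 53.3 at 6 DAP, against 154, 52 and 20.05 at 3 DAP, 109, 40.8 and 7.86 at 4 DAP and 2.20, 5.80 and 0.209 in 8 DAP endosperm. aos1 had 79.1, 47.5, 135 and 13.6 at 3, 4, 6 and 8 DAP. The lipoxygenase gene lox10 instead had its highest value, 50.4, at 0 DAP, and 19.9 at 6 DAP. The alcohol dehydrogenase gene adh2 was at 230.3 at 6 DAP and 28.6 at 8 DAP, and the caffeoyl-CoA methyltransferase gene ccoaomt1 at 132 and 16.2. The receptor kinase gene ERECTA also had its highest value, 451, at 0 DAP, and then 177 at 4 DAP, 27.8 at 6 DAP and 20.1 at 8 DAP.

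Of the 7 explanations tested below, those on the 6 DAP library and on depth were written before the result was seen, and the other 5 tests were chosen after it.

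Zeins and some other late endosperm transcripts were counted in the 0 to 4 DAP kernels and hardly at 6 DAP: the 27 abundant zeins had 38069 to 47245 reads in each of the 5 early libraries and 134 at 6 DAP. If reads had been carried over from the 10 and 12 DAP libraries in fixed shares, shares fitted on zeins (0.0553% to 0.0646% of the 12 DAP value) would predict other late genes. Over 85 unnamed models (31 with like counts in another model) with v of at least 1000 at 12 DAP and under 1 at 6 DAP they missed by a median of 1.53 on the log2 scale (1.46 with a weighted linear fit, and 1.36 over 66 models with 1 per group of like counts, a set chosen later), 1.52 to 3.13 by library and above the limit of 1 set for excluding it, so uniform carry-over does not account for those models as a set. Some of the 85 may be zeins outside the list, since unlisted models that count like listed zeins were not left out. For the zeins themselves, on which the shares were fitted, carry-over may still hold, and a later choice of 7 named genes, such as sh2 and o2, missed by 0.95, between the limits of 0.5 and 1, and decides nothing. Sharing of reads between models of like counts is argued against by 71 models without such a partner, whose 4 DAP values were at the median 14.95 times those at 6 DAP (lower quartile 2.31), while sharing with copies of other counts, which was not checked, and a biological origin in young kernels stay open. Some of the 71 may also be zeins outside the list that share reads with listed ones at other counts.

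The step from 6 to 8 DAP is the largest under TMM, with 2182 genes, though by library total it held 2824 genes and the step from 10 to 12 DAP 2830. A difference in depth is argued against, since 2193 genes passed after thinning to the smallest total, against at most 706 in any other step. Skipping the 6 DAP library, 1966 genes passed between 4 and 8 DAP, against 2182 between 6 and 8 DAP, a value between the limits set for and against an unusual 6 DAP library. Removal of maternal tissue by dissection may contribute: the 9 maternal reproductive MADS genes had a median log2 change of -2.36 from 6 to 8 DAP and of 0.10 from 4 to 6 DAP. Age could give the same, and age and tissue cannot be told apart in this design.

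By library total most genes are lower at 12 than at 8 DAP, with a median log2 change of -2.36 over 19942 models with v of at least 10, against -0.14 under TMM. Totals without the 100 most counted models of each library (311 models in all) gave -0.31, which follows from the shares of 19.6% and 85.8% already seen for the 100 most counted models of the 8 and 12 DAP libraries, so it is no separate test of a few genes taking most of the counts. Counting each group of like counts once moved the median by 0.20, to -2.16, so most of the shift by library total remained. The size of this move is bounded by the shares of reads that these models held, 3.87% at 8 DAP and 39.5% at 12 DAP. It is therefore no separate test of reads counted in several near-identical models, and copies of other counts were not checked. Whether RNA of these genes per cell fell as zein RNA rose was not tested.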
